A study of Mus musculus with 6 samples.

How the data were processed

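The deposited files comprised a table of UMI counts with cells in rows and genes in columns, a cell table and a receptor table, each covering both lanes. The deposited counts were whole UMI numbers per cell and gene, as every value was a whole number of at least 0. In the deposited cell table, the hashtag counts and the hashtag fraction gave the counts of the main hashtag of a cell and its share of all hashtag counts, and the other columns gave the gate, the hashed replicate, the total UMIs and the cluster number. The deposited receptor table gave junction sequences, V and J genes and the UMI counts behind each chain. Cells came from digested colonic lamina propria and were sorted per the labels' protocols, with a viability above 80%. Triplicates of a gate were hashed with TotalSeq-C reagents and loaded on 1 lane, per the labels' protocols, which name 3′ v3 or 5′ v2 chemistry without saying which was used here. Per the submitters' processing notes, Cell Ranger and Scanpy 1.7.2 were used with the builds mm10 and GRCm38. The Cell Ranger version, the filters on cells and genes, the clustering settings and the hashtag rule were not given in the sources used here. From the values, listed genes were seen in at least 10 cells, the lowest number of genes per cell was 399, and the lowest main hashtag share among assigned cells was 0.8.

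The 3 hashtag features, which took 43.8% of UMIs, were left out of the counts. The deposited total equalled the sum of a cell's counts with hashtags in all 23595 cells. Cells without a hashed replicate (4721) were left out, as were 216 assigned cells without a cluster from all results by class. No doublet caller was run, and cells with counts from several hashtags fall among those left out. Of 17878 receptor rows, 17863 were found in the cell table, all with the same gate there. Summed UMIs were 23289046, 13610295 and 7925662 for replicates 1 to 3 of the tdTomato-GFP- gate and 7424984, 20153550 and 9967811 for those of the tdTomato+GFP+ gate, with medians of 3905, 3778.5 and 3847 and of 3771, 3655 and 3501.5 UMIs per cell. Cells with both receptor chains numbered 3713, 2219 and 1267, and 1377, 3089 and 1645. Gate names in the deposited tables assign the cells to the groups, per the labels.

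Test designs, gene lists, markers and most alternatives were written before the data were examined. Clusters are those of the authors. A cluster took a class name where at least 3 markers and at least 50% of the markers of the class reached 20 CPM and 1.5-fold over the median of the other clusters, with 20 CPM added before folds. Its 10 leading genes also had to hold a marker of the class, not more markers of another class, and no lead of stress or other tissue genes. These thresholds were set after the data were seen. Clusters 5 and 6 passed as Treg-like and Th1-like by their markers but held more markers of another class among their 10 leading genes, so they are compared by number. Clusters 4, 8, 11 and 14 stayed unnamed. Classes with at least 20 cells in each of the 6 replicates were compared between gates.

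Raw UMI counts were summed per hashed replicate and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, TMM factors, filterByExpr with a minimum count of 10, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. CPM of genes are UMI counts scaled to the TMM-adjusted total of tested genes in the replicate, those of Foxp3 by class, of Il17a in cells without a cluster and of markers of other cell types are scaled to the total without hashtags, and log2 fold changes are those of tdTomato+GFP+ over tdTomato-GFP- cells with their standard errors (SE). In the comparison with Foxp3 UMI-positive cells Foxp3 itself was left out of the results, since it selects the cells. A gene was called separated where all 3 replicates of one gate lay above those of the other. Where a gate had 0 UMIs, the fold is a floor set against 3 counts, and for 1 to 3 counts the ratio has a 95% counting interval. Gene lists were tested with camera of limma 3.58.1 at a correlation of 0.01, with fry beside it, on log-CPM with a prior count of 2, for lists with at least 3 tested genes and with adjustment over lists. They comprised Treg core, effector and tissue Treg, Th17, Th1, Th2, Tfh, naive and central memory, cytotoxic, effector cytokine, TCR activation, inhibitory receptor, IL-2 and STAT5, TGF-beta, type I interferon, cell cycle, chemokine receptor, glycolysis, oxidative phosphorylation, cholesterol synthesis, apoptosis, AP-1 and stress and mitochondrial genes, and markers of B and plasma, myeloid, epithelial, NK and ILC, gamma delta, innate-like, stromal, CD8, erythroid and mast cells. Differences of the gate effect between classes were tested in edgeR with an interaction term.

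Named genes follow a rule fixed in advance. It takes the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p below 0.05, separated replicates and a mean of at least 20 CPM in the higher gate. It leaves out immunoglobulin and receptor genes, Gm and Rik genes, ribosomal and mitochondrial genes. To these it adds up to 2 risen and 2 fallen members of each list with the smallest adjusted p, and a fixed set (Foxp3, Il2ra, Ctla4, Ikzf2, Gata3, Tbx21, Il10, Il17a, Ifng, Il4, Il13, Il2, Pde3b, Satb1, Tcf7, Cd4, Cd40lg and Xist). 2 genes that this rule names and 1 of the lists are not reported here, and the counts over named genes leave those 2 out. Coordinates are those of GENCODE M21 on GRCm38, counted from 1, and 11828 of 11955 tested genes had 1 position there.

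Shares of cells were compared with a two-sided exact permutation test of 3 against 3 replicates and adjusted over classes. Foxp3 detection was also computed after drawing 2000 UMIs from each cell, leaving out cells with fewer. For clonal expansion 1267 cells with both chains were drawn per replicate, 200 times. V genes were tested with edgeR on clonotypes per V gene, fitted per chain and adjusted over alpha and beta genes together. The spread of clonotypes over classes was set against 1000 shuffles of class labels within replicate. Whether replicate numbers pair the samples of the 2 gates is not given in the labels. Clonotypes shared at equal numbers (75, against 37 under the best other assignment) were used to check this. So was the correlation across genes of all-cell deviations from the gate means (0.264, 0.148 and 0.275 at equal numbers, -0.115 on average otherwise). It was highest at the own number for all 6 replicates. Both checks point to replicates of equal number as samples of the same animal. The main tests, edgeR and exact permutation alike, do not use this pairing. A fit with replicate number as a block was run as an alternative. For named genes, 356 results kept direction and side of the threshold under the block, 22 became stronger and 10 weaker.

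On simulated data with 200 changed genes at the depth and dispersion of the all-cell sums, 31.3%, 79.1% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold were called, with 9 false calls. For Th17-like cells the shares were 41.8%, 79.1% and 95.5% with 3 false calls, and for cluster 5 they were 17.9%, 50.7% and 87.9% with 6 false calls. For V genes changed 4-fold, 5 of 6 alpha and 3 of 3 beta genes were called. Alternatives comprised DESeq2 1.42.0 with its size factors, upper-quartile normalization, no filter on low counts, a 1.5-fold minimum with glmTreat, the replicate block, each replicate left out in turn, cells with a paired receptor only, equal numbers of cells per cluster, Foxp3 UMI-positive cells or cluster 5 of both gates, at least 2 Foxp3 UMIs, and cells below the 99th percentile of UMIs. Alternatives chosen after seeing the data were clustered cells only, cells without clusters 8, 11 and 14, 1 cell per clonotype, cluster 5 of the tdTomato-GFP- gate as reference, and the replicate block for V genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.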

Results

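CD4 T cells of the colonic lamina propria were taken from mice heterozygous for an X-linked Foxp3 allele with an EGFP and iCre insert, in the presence of a Cre-dependent tdTomato reporter. Foxp3 encodes the transcription factor that defines regulatory T (Treg) cells. In such females each T cell uses either the inserted allele, read here as a reporter allele without Foxp3 protein, or the intact allele. The tdTomato+GFP+ gate therefore holds cells that transcribe the inserted allele. The tdTomato-GFP- gate holds CD4 T cells with neither reporter, among them Treg cells that use the intact allele. Cells with a single reporter fall in neither gate. Each gate came as 1 10x lane with 3 hashed biological replicates, so gate and lane cannot be told apart in any comparison made here. The deposited table held 23595 cells and 15473 genes. Of these cells, 18874 were assigned to a hashed replicate, 8765 in the tdTomato+GFP+ gate (1747, 4610 and 2408 in replicates 1 to 3) and 10109 in the tdTomato-GFP- gate (5159, 3114 and 1836). Median UMIs per assigned cell were 3632 and 3860 in that order, and 13310 assigned cells carried both an alpha and a beta receptor chain. All comparisons rest on n = 3 hashed replicates per gate. The main tests do not use the pairing by replicate number, so a gene that did not pass may pass with replicate number as a block.

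Foxp3 itself, the target gene, differed between the gates in opposite directions by cell class. Its gene lies on chromosome X, 7573644 to 7595245 (GRCm38). Over all cells its mean was 179 CPM (SD 13.4) in tdTomato-GFP- and 126 CPM (SD 16.0) in tdTomato+GFP+ cells (log2 fold change -0.52, SE 0.10, adjusted p = 0.00594), while the share of cells with a Foxp3 UMI was higher in tdTomato+GFP+ cells, 34.1% (SD 3.36) against 21.3% (SD 2.09), and 21.2% against 17.2% after thinning every cell to 2000 UMIs. With equal numbers of cells per cluster in both gates the all-cell fold was -0.07 and did not pass. In cluster 5, the cluster whose cells carry Treg markers, Foxp3 fell from 839.6 CPM (SD 65.6) to 191 CPM (SD 33.1, log2 fold change -2.13, SE 0.16, adjusted p = 7.75e-07), and 79.3% against 36.8% of cells had a UMI (69.2% and 26.1% thinned). In Th17-like cells it rose from 35.4 CPM (SD 18.2) to 144 CPM (SD 12.2, log2 fold change 1.82, SE 0.30, adjusted p = 0.0255), with a UMI in 6.63% and 36.4% of cells (3.76% and 23.2% thinned). Cells without a cluster number, rich in B and plasma cell transcripts, served as a rough measure of background. They had a Foxp3 UMI in 6.23% (SD 5.46) and 15.8% (SD 11.2) of cells (4.69% and 8.16% thinned) at median depths of 4771.7 and 4685.7 UMIs. The share in Th17-like cells of the tdTomato-GFP- gate lay near that of these cells, a background known only roughly. Some of these cells carried both receptor chains, so they are not free of T cells. In tdTomato-GFP- cells whose receptor also occurred in the other gate the share was lower, 2.35% (SD 0.666). The Th17-like share is thus not shown to be background. Median depths were 3956.5 and 3517.2 UMIs in Th17-like cells and 3431.5 and 3659.3 UMIs in cluster 5. The Th2-like cells (74.9 and 93.2 CPM) and cluster 6 (71.6 and 129.5 CPM) gave folds that did not pass, though that of cluster 6 passed with replicate number as a block (log2 fold 0.75, adjusted p = 0.0480, up to 1.0 over 12 alternatives). In both of these, and in the Th17-like cells and cluster 5, the shares of the 3 replicates did not overlap between the gates (exact permutation test, two-sided, p = 0.1, the smallest value that 3 against 3 allows). The Th17-like rise did not pass with the 1.5-fold minimum of glmTreat, and its call held in 7 of 12 alternative settings.

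**Figure D1:**
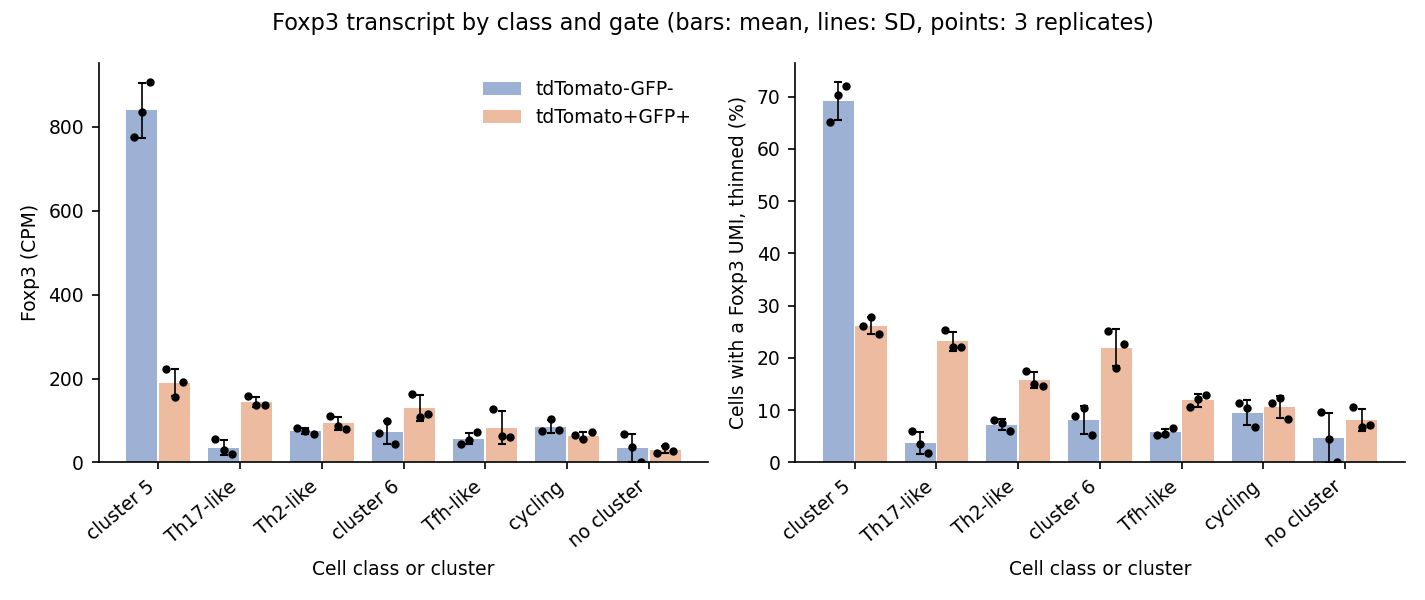
Foxp3 level in CPM and share of cells with a Foxp3 UMI after thinning to 2000 UMIs, for 6 classes and for cells without a cluster, in the tdTomato-GFP- (blue) and tdTomato+GFP+ gate (orange), with bars for the mean, lines for the SD and points for the 3 replicates. Cluster 5 is lower in tdTomato+GFP+ cells (191 against 839.6 CPM), while Th17-like cells are higher (144 against 35.4 CPM).

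The make-up of the gates by cell class was compared next. Th17-like cells, named by markers such as transcripts of the cytokines Il17a and Il17f, made up 65.4% (SD 7.39) of tdTomato+GFP+ and 11.2% (SD 1.56) of tdTomato-GFP- cells. Clusters 1, 2 and 3 held most of them in tdTomato+GFP+ cells (2096, 1599 and 1460 cells), as did clusters 2, 3 and 1 in tdTomato-GFP- cells (476, 341 and 273 cells), and Il17a, Ccl20 and Il17f led all 5 of the Th17-like clusters. Several other classes held a smaller share of tdTomato+GFP+ cells. The shares of a gate add up to a whole, so the larger Th17-like share lowers the others. Shares among the cells that are not Th17-like were not computed, so no class is shown to shrink among them. Cluster 5 held 1.84% against 14.4% of cells, Th2-like cells 9.37% against 20.3%, Tfh-like cells 1.22% against 7.87% and naive or central memory-like cells 0.633% against 7.66%. Cytotoxic-like cells made up 0.251% against 1.41%, and cycling cells 2.40% against 3.71%. Among clusters that no marker rule named, cluster 4 (led by Ccl5, Csf2 and Gzma) held 4.86% against 11.8%, cluster 11 (led by Lars2, Reg3b and Acta2) 1.71% against 2.43%, and cluster 14, whose median depth was 1090.0 UMIs, 0.751% against 1.54%. For each of these the 3 replicates of one gate lay apart from those of the other (exact permutation p = 0.1, adjusted p = 0.13). Cluster 6, with the Th1 transcripts Ifng and Tbx21 but also the cytotoxic transcripts Gzmk and Fasl, held 7.35% against 9.17%. Cluster 8, led by Dcn and the heat shock gene Hspa1b, held 3.23% against 7.23% (exact permutation p = 0.3 for both). The sort itself sets these shares, the genes that define the clusters differ between the gates, and the thresholds that left clusters 4, 8, 11 and 14 unnamed were set after the data were seen.

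**Figure D2:**
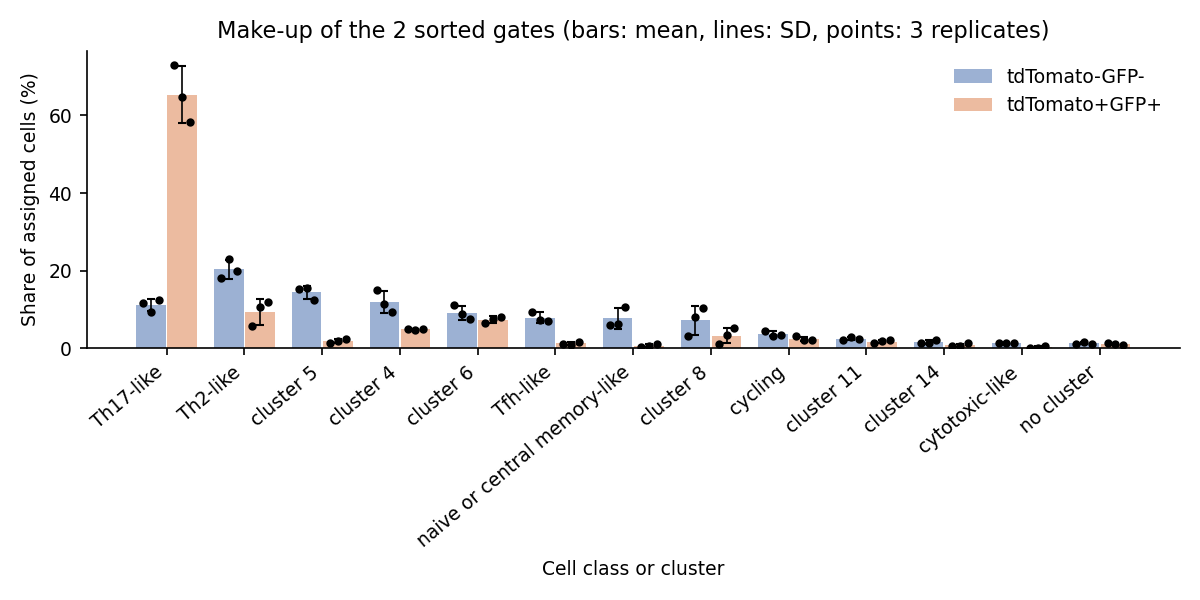
Share of assigned cells in each cell class or cluster for the tdTomato-GFP- (blue) and tdTomato+GFP+ gate (orange), with bars for the mean, lines for the SD and points for the 3 replicates. Th17-like cells make up 65.4% of the tdTomato+GFP+ and 11.2% of the tdTomato-GFP- gate.

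Over all cells, 1550 genes were higher and 1603 lower in tdTomato+GFP+ than in tdTomato-GFP- cells among 11933 tested (edgeR, adjusted p below 0.05), with 4476 at an unadjusted p below 0.05. The replicates of the gates were fully separated at 43.1% of genes, where chance gives 10%. Transcripts of Th17 effectors were among those that rose. Il17a (chromosome 1, 20730905 to 20734496) went from 1737 to 10836 CPM (log2 fold change 2.64, SE 0.17, adjusted p = 0.000498), Il17f from 246 to 1419 CPM (log2 fold change 2.53, SE 0.25, adjusted p = 0.00241), and Ccl20, the chemokine ligand of Ccr6, from 140.3 CPM (SD 51.5) to 2231 CPM (SD 116, log2 fold change 3.99, SE 0.36, adjusted p = 0.00271). Tmeff2 showed the largest fold, with 4 UMIs in tdTomato-GFP- and 778 in tdTomato+GFP+ cells (log2 fold change 7.89, SE 0.99, adjusted p = 0.00532). Other large rises were those of Vdr, the vitamin D receptor, on chromosome 15, 97854425 to 97910630 (log2 fold change 3.73, SE 0.22, adjusted p = 0.000129), of the synaptic vesicle gene Syp (3.09), of Prr5l (2.79), of the costimulatory ligand Cd86 (2.72), of Plek (2.60) and of the peptide processing gene Cpe (2.41 log2). Among the largest falls were those of Itgae, which encodes the CD103 integrin chain and lies on chromosome 11, 73090583 to 73147446 (from 59.4 to 3.43 CPM, log2 fold change -4.09, SE 0.29, adjusted p = 0.000453), of Pglyrp1 (-3.52), Trat1 (-3.24), the follicular homing receptor Cxcr5 (-3.05), the granzyme gene Gzmk (-3.02), Igfbp4 (-2.88), the naive T cell factor Lef1 (-2.74), the Th1 chemokine receptor Cxcr3 (-2.70) and Gramd3 (-2.57 log2). Of the genes fixed in advance, Ikzf2, which encodes Helios (chromosome 1, 69531214 to 69687245), fell (log2 fold change -2.19, SE 0.08, adjusted p = 6.96e-06), as did the Th1 factor Tbx21 (-1.19), Ifng (-1.54), Tcf7 (-1.56), the chromatin organizer Satb1 (-1.61) and Cd40lg (-0.62 log2). The inhibitory receptor Ctla4 (0.92) and Cd4 (0.50 log2) rose. Those that did not pass had log2 folds of 0.26 for Il2ra, -0.58 for Gata3, 0.56 for Il10, 0.50 for Il4, 0.48 for Il13, -1.13 for Il2, 0.08 for Pde3b and -0.01 for Xist.

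The all-cell result depends strongly on which cells are compared. With the same number of cells per cluster in both gates, which leaves 1071, 1843 and 1165 cells in replicates 1 to 3 of each gate, 93 genes were higher and 189 lower. Of the 3153 calls over all cells 261 were kept there, against 1378 with 1 cell per clonotype. Calls ended for Il17a (log2 fold 0.33), Il17f (0.47), Prr5l (1.51), Cd86 (1.65), Plek (1.91), Cpe (1.22), Itgae (-2.86), Igfbp4 (-0.86), Lef1 (-1.27), Cxcr3 (-1.86), Gramd3 (-1.42), Tcf7 (-0.54), Cd40lg (-0.45), Ctla4 (0.36) and Cd4 (0.11). They held for Ccl20 (2.16), Vdr (2.96), Syp (2.80), Pglyrp1 (-2.12), Trat1 (-2.17), Cxcr5 (-1.39), Gzmk (-2.12), Ikzf2 (-1.42), Tbx21 (-1.27), Ifng (-2.29) and Satb1 (-1.28). With replicate number as a block Igfbp4 (adjusted p = 0.0563) and Cxcr3 (0.0827) did not pass either, and over all 17 alternatives their adjusted p reached 0.656 and 0.199.

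Among the gene lists fixed in advance, 9 of 16 Th17 genes rose and 1, Il22 (-1.80), fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.000903, and adjusted p = 0.441 with an estimated correlation). Il22 did not pass with replicate number as a block. Naive and central memory genes fell in 13 of 15 cases, or 14 adjusted over the list alone, including the egress receptor S1pr1 (-1.58) beside Lef1 and Tcf7 (adjusted p = 1.71e-07; adjusted p = 0.332 with an estimated correlation). Cytotoxic genes fell in 11 of 15, or 12 adjusted over the list alone, with Klrc1 (-3.22) and Klrk1 (-1.23) as examples (adjusted p = 7.53e-07; adjusted p = 0.332 with an estimated correlation). Th1 genes fell in 7 of 15 and rose in 2, Cxcr6 (0.67) and Il18rap (0.24), with adjusted p = 0.0265 and adjusted p = 0.441 with an estimated correlation. Tfh genes fell in 7 of 14, such as Sh2d1a (-1.32) and Btla (-1.42), with adjusted p = 0.0265, 0.104 with replicate number as a block, and adjusted p = 0.521 with an estimated correlation. Interferon response genes fell in 8 of 18, or 13 adjusted over the list alone, with Usp18 (-1.99) and Ifi206 (-1.39) named (adjusted p = 3.68e-05; adjusted p = 0.487 with an estimated correlation). Apoptosis regulators fell in 10 of 21, among them Bcl2 and the death receptor gene Fas (-1.52), whereas Bad (0.55) rose (adjusted p = 0.00555; adjusted p = 0.332 with an estimated correlation). TGF-beta response genes fell in 8 of 15, with Cd101 at -1.08 (adjusted p = 0.0432, 0.0891 with replicate number as a block, and adjusted p = 0.441 with an estimated correlation). Small rises were found for 5 of 27 oxidative phosphorylation genes, such as Uqcr10 (0.37; adjusted p = 0.0265, and adjusted p = 0.521 with an estimated correlation), and for 3 of 19 cholesterol synthesis genes, such as Mvd (0.90; adjusted p = 0.0266, and adjusted p = 0.759 with an estimated correlation). Mitochondrially encoded genes fell in 8 of 13 (adjusted p = 0.00126; adjusted p = 0.487 with an estimated correlation). The lists were tested on all-cell sums, so the make-up of the gates enters them. Th17-like cells held a larger share of the tdTomato+GFP+ gate, and naive, Tfh-like and cytotoxic-like cells a smaller one. No list result at equal cells per cluster is given here, so these are not shown to be changes within cells. All 9 splits that mix the gates called lists too, as given further below, so the camera adjusted p alone does not show a gate difference.

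The Treg core list was not called, with 6 of 25 genes up and 10 down (adjusted p = 0.143). The surface receptor Lrrc32 (-4.54) fell, while Sdc4 (1.34) and Socs2 (1.51) rose. Effector and tissue Treg genes split into 5 up, such as Prdm1 (0.92) and Nfil3 (0.77), and 3 down, such as Dgat2 (-3.24) and Penk (-1.64, not passing with replicate number as a block), of 20 (adjusted p = 0.759). Further lists that were not called were chemokine receptors and gut homing (6 up and 10 down of 23, adjusted p = 0.13; Ccr1 1.90, Ccr8 -1.38), TCR activation (5 and 8 of 21, adjusted p = 0.167; Nr4a2 -1.96) and inhibitory receptors (5 and 5 of 14, adjusted p = 0.867; Entpd1 0.69). The IL-2 and STAT5 response (3 and 7 of 17, adjusted p = 0.494; Socs3 -1.24), glycolysis (5 and 3 of 17, adjusted p = 0.194; Tpi1 0.56, Hk2 -0.87), effector cytokines (4 and 5 of 20, adjusted p = 0.874), Th2 (2 and 1 of 12, adjusted p = 0.826; Ccr4 0.49), cell cycle (0 and 1 of 30, adjusted p = 0.255; Hmgb2 -0.49) and AP-1 and dissociation stress (3 and 2 of 21, adjusted p = 0.759) were not called either. Markers of other cell types were also summed. Gamma delta T cell markers, which include genes also made by Th17 cells, summed to 298 CPM (SD 28.0) in tdTomato+GFP+ and 117 CPM (SD 24.5) in tdTomato-GFP- cells (exact permutation p = 0.1), and stromal markers to 257 CPM (SD 162) and 88.1 CPM (SD 29.2, exact permutation p = 0.2). Innate-like markers summed to 221 CPM (SD 2.83) and 194 CPM (SD 10.8, exact permutation p = 0.1). Among clustered cells, on which all results by class rest, B and plasma cell markers summed to 81.4 CPM (SD 6.60) and 218 CPM (SD 41.8, exact permutation p = 0.1). Over all assigned cells mitochondrial transcripts summed to 7641 and 8698 CPM (exact permutation p = 0.1). As lists, the markers of gamma delta T cells (adjusted p = 0.43), stromal and endothelial cells (0.833), epithelial cells (0.281), B and plasma cells (0.759), myeloid and dendritic cells (0.759), NK cells and ILC (0.065) and innate-like alpha beta T cells (0.286) were not called. The CD8 T cell, erythroid and mast cell markers, too few for a test, stood at 4.70, 0.327 and 10.996 CPM in tdTomato+GFP+ and 7.24, 0.243 and 18.3 CPM in tdTomato-GFP- cells. The list median, mean and test differed in sign for effector and tissue Treg, Th2, effector cytokine, inhibitory receptor, IL-2 and STAT5, myeloid and stromal genes.

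To compare cells of the inserted allele with cells that transcribe the intact one, all tdTomato+GFP+ cells were set against the tdTomato-GFP- cells with at least 1 Foxp3 UMI (1126, 719 and 349 cells). In tdTomato+GFP+ cells 1061 genes were higher and 1353 lower among 11020 tested, with 3791 at an unadjusted p below 0.05 and 40.3% of genes separated. Only the tdTomato-GFP- side was selected by a Foxp3 UMI, and the sides differ in their clusters, so the sides differ by selection as well as by gate. With a Foxp3 UMI required in both gates 920 genes were higher and 1127 lower, and 1857 of the 2414 calls were kept. Lrrc32, a receptor that holds latent TGF-beta on Treg cells, fell from 70.9 to 0.862 CPM (log2 fold change -6.42, SE 0.33, adjusted p = 3.62e-05), and Itgb8, which helps release TGF-beta, fell by 5.14 log2 units. Large falls were also those of Itgae (-5.95), Ky (-5.30), Epcam (-4.82), Pglyrp1 (-4.82), the tissue Treg receptor Klrg1 (-4.18), Tff1 (-3.70), Ikzf2 (-3.65) and Hspb1 (-3.35 log2). In the other direction Il17a rose from 483 to 10921 CPM (log2 fold change 4.50, SE 0.17, adjusted p = 3.47e-05) together with Ccl20 (log2 fold change 4.85, SE 0.29, adjusted p = 0.000507), Il17f (4.46), Igfbp7 (4.64), Plxdc2 (4.41), Vdr (3.96), the kinase gene Blk (3.92), Prr5l (3.82), Cpe (3.25) and Vax2 (3.03 log2). Pde3b, a phosphodiesterase gene repressed by Foxp3, rose (log2 fold change 2.07, SE 0.14, adjusted p = 2.03e-05), as did Cd40lg (1.09), Cd4 (0.73) and Tcf7 (0.53 log2). Il2ra, the high-affinity IL-2 receptor chain, fell (log2 fold change -1.02, SE 0.16, adjusted p = 0.00535), with Il10 (-1.16) and Satb1 (-1.06 log2). Not passing were Ctla4 (0.26), Gata3 (-1.17), Tbx21 (-0.35), Ifng (0.42), Il4 (1.35), Il13 (2.98), Il2 (1.48) and Xist (-0.03 log2).

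By list, 16 of 24 Treg core genes fell, or 17 adjusted over the list alone, among them Tnfrsf18 (-1.50) and Izumo1r (-2.17), and 2 rose, Socs2 (1.12) and Sdc4 (0.47). The list's camera adjusted p was 1.14e-06, and adjusted p = 0.216 with an estimated correlation. Effector and tissue Treg genes fell in 8 of 19, for example Ccr8 (-2.66), with adjusted p = 0.00387 and adjusted p = 0.216 with an estimated correlation. Th17 genes rose in 8 of 16, or 10 adjusted over the list alone, with Ahr (0.75) as a further example (adjusted p = 1.31e-05; adjusted p = 0.266 with an estimated correlation). Effector cytokine genes rose in 7 of 20, including Il21 (2.10) and Tnfsf8 (2.51), while Ebi3 (-2.41) fell (adjusted p = 0.00387; adjusted p = 0.283 with an estimated correlation). Interferon response genes fell in 15 of 18, such as Rtp4 (-1.80) and Isg20 (-1.12), with adjusted p = 2.19e-08 and adjusted p = 0.216 with an estimated correlation. Cholesterol synthesis genes rose in 5 of 19, with Sqle at 0.57 (adjusted p = 0.000931; adjusted p = 0.521 with an estimated correlation). Gamma delta T cell markers rose in 3 of 5 (adjusted p = 0.00948; adjusted p = 0.216 with an estimated correlation). With replicate number as a block Il17f (adjusted p = 0.0777, up to 0.26 over 17 alternatives), Il10 (0.0541, up to 0.603), Il2ra (0.112, up to 0.141) and Tff1 (0.0938, up to 0.559) did not pass. Cluster 5 of both gates alone, with fewer cells, gave 98 genes higher and 142 lower. There Il17f (3.41), Cpe (1.79), Epcam (-2.61), Pglyrp1 (-2.68), Klrg1 (-0.73), Tff1 (-1.88), Ikzf2 (-2.43), Hspb1 (-3.33), Il10 (-0.32), Tcf7 (0.78), Il2ra (-0.68), Satb1 (-0.68) and Cd4 (0.40 log2) did not pass. Apart from those of Hspb1 and Tcf7, these folds were also smaller in size than against all Foxp3 UMI-positive cells. The lower number of cells alone thus does not account for the lost calls.

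Within the Th17-like class the gates differed at 479 genes higher and 650 lower in tdTomato+GFP+ cells among 10075 tested, with 2388 at an unadjusted p below 0.05 and 29.3% of genes separated. Here the lineage cytokine Il17a differed little, from 12894 to 16318 CPM (log2 fold change 0.34, SE 0.04, adjusted p = 4.71e-05), while 3 other cytokine transcripts fell. Ifng (chromosome 10, 118441046 to 118445892) fell from 927 to 121 CPM (log2 fold change -2.93, SE 0.19, adjusted p = 0.00106), Csf2, which encodes GM-CSF, from 82.6 to 9.03 CPM (log2 fold change -3.23, SE 0.18, adjusted p = 5.24e-07), and Il22, a cytokine that acts on epithelium, from 715 to 61.1 CPM (log2 fold change -3.53, SE 0.46, adjusted p = 0.0167). Il2ra rose (log2 fold change 1.11, SE 0.12, adjusted p = 1.9e-05), as did Ccl20 (2.12), the Treg genes Fgl2 (1.59) and Entpd1 (1.07) and Ctla4 (0.28). Flicr, a long noncoding RNA of the Foxp3 locus, rose as well (log2 fold change 3.08, SE 0.40, adjusted p = 0.000545). Mstn had 0 UMIs in tdTomato-GFP- and 530 in tdTomato+GFP+ cells, a level at least 38.4-fold higher. Other large rises were those of Gldc (4.39), Prg4 (3.58), Igfbp7 (3.37), Syp (3.04), Vdr (2.91), Glp1r (2.60), Plac8 (2.59) and Plek (2.42 log2). Large falls were those of Cxcr3 (-3.59), Ermn (-3.28), Ctsw (-2.69), Ly6g5b (-2.50), Kcnc1 (-2.37), St3gal6 (-2.28) and Kit (-2.21 log2). Satb1 (chromosome 17, 51736187 to 51833290) fell by 1.92, Cd40lg by 1.27, Tbx21 by 1.16, Ikzf2 by 1.04 and Tcf7 by 0.81 log2 units, and Il10 (1.36) did not pass.

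By list in Th17-like cells, Th1 genes fell in 8 of 14, or 9 adjusted over the list alone (camera adjusted p = 4.62e-06; adjusted p = 0.381 with an estimated correlation). Th17 genes themselves fell in 9 of 16 and rose in 2, Il17a and Ccl20. The fallen ones included the cytokine receptor genes Il23r (-1.22), Il1r1 (-1.40) and Il17re (-1.89), with adjusted p = 0.00761 and adjusted p = 0.479 with an estimated correlation. Treg core genes rose in 8 of 21, among them Socs2 (1.23), and fell in 3, among them Itgae (-2.24) and Icos (-0.32), with adjusted p = 0.0137 and adjusted p = 0.479 with an estimated correlation. Apoptosis regulators fell in 7 of 19, including Fas (-1.93) and Bcl2l11 (-1.43), with adjusted p = 0.00301 and adjusted p = 0.381 with an estimated correlation. With replicate number as a block the count was 1726, while Cxcr3 (adjusted p = 0.114), Il22 (0.085) and Ccl20 (0.0956) did not pass. Over 12 alternatives the adjusted p of Cxcr3 reached 0.114 and that of Il22 0.085.

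**Figure D3:**
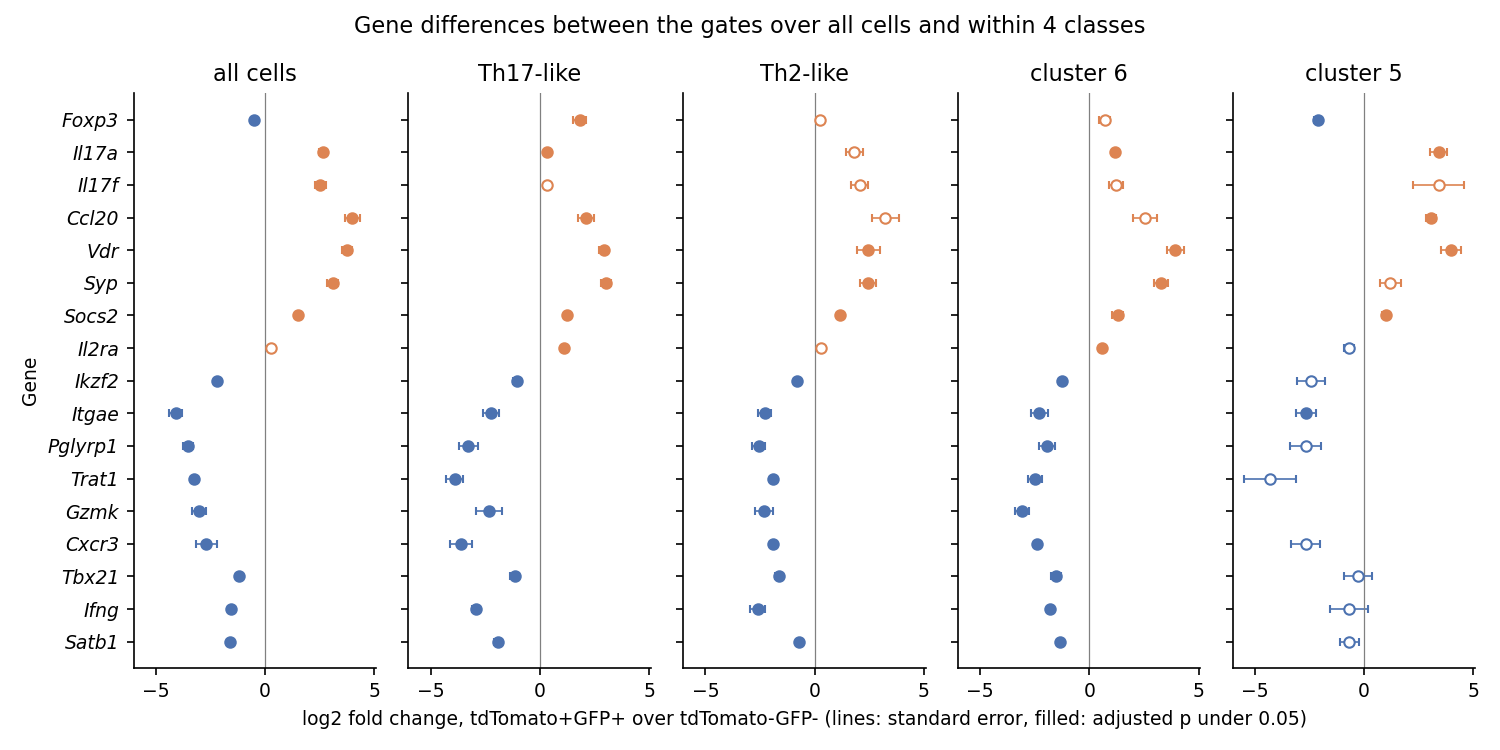
Log2 fold change between the tdTomato+GFP+ and tdTomato-GFP- gate for 17 genes, chosen after their values were seen, over all cells and within Th17-like cells, Th2-like cells, cluster 6 and cluster 5, with lines for the standard error and filled points for an adjusted p under 0.05. Vdr is higher in all 5 panels (3.73, 2.91, 2.45, 3.94 and 3.97), while Foxp3 is higher in Th17-like cells (1.82) and lower in cluster 5 (-2.13).

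Cluster 5, which carries 9 Treg markers but is led by more markers of another class, held 162 tdTomato+GFP+ and 1496 tdTomato-GFP- cells and gave 98 genes higher and 143 lower in tdTomato+GFP+ cells among 6491 tested (22.8% separated). Besides Foxp3, other genes fell. Lrrc32 (chromosome 7, 98489283 to 98502181) was seen with 367 UMIs in tdTomato-GFP- and 3 in tdTomato+GFP+ cells, a ratio of CPM of 13.8 (95% counting interval 4.7 to 67.1), Ky had 334 and 0 UMIs (at least 12.5-fold lower) and Ankrd55 118 and 0 UMIs (at least 4.4-fold lower). These floors and intervals cover counting error only. Frmd5 was lower by a ratio of 30.1 (interval 5.3 to 1191.7) and Art2b by a ratio of 22.2 (interval 3.9 to 880.4). Itgb8 (-2.83), Itgae (-2.66), Rgs16 (-3.04), Nr4a2 (-2.79), Cd81 (-2.30) and Lef1 (-2.50 log2) fell as well. Il17a went from 90.6 to 1018 CPM (log2 fold change 3.40, SE 0.37, adjusted p = 0.00773), the type 2 cytokine Il13 rose by 4.16, the IL-25 receptor gene Il17rb by 2.91 and Ccl20 by 3.06 log2 units. Impg1 (5.36), Igfbp7 (4.03), Myo6 (4.01), Vdr (3.97), Plac8 (3.88), Tnfsf8 (2.83), Cd40lg (2.19) and Pde3b (2.11 log2, chromosome 7, 114415281 to 114539251) rose too. Ikzf2 (-2.43), Il2ra (-0.68) and Il4 (adjusted p = 0.144) did not pass, the last 2 passing with replicate number as a block. Treg core genes fell in 5 of 22, or 12 adjusted over the list alone (camera adjusted p = 2.94e-05; adjusted p = 0.485 with an estimated correlation). Effector cytokine genes rose in 5 of 17 (adjusted p = 0.000112; adjusted p = 0.219 with an estimated correlation). The tdTomato+GFP+ side rests on 24, 80 and 58 cells.

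Th2-like cells differed at 73 genes higher and 158 lower in tdTomato+GFP+ cells among 9064 tested (18.5% separated), or 363 genes in all with replicate number as a block. The type 2 genes Gata3 (0.57), Il4 (1.11) and Il13 (1.11) did not pass. Cd7 (log2 fold change -3.47, SE 0.50, adjusted p = 0.0351), Ifng (-2.60), Gzma (-2.48), Cd160 (-2.45), Il12rb2, a chain of the IL-12 receptor (-2.42), Gzmk (-2.30), Itgae (-2.28), Cxcr3 (-1.91), Tbx21 (log2 fold change -1.65, SE 0.18, adjusted p = 0.000116), Fasl (-1.20), Ikzf2 (-0.83) and Satb1 (-0.72 log2) fell. Ifng did not pass with replicate number as a block (adjusted p = 0.0808, up to 0.172 over 12 alternatives). Nipal1 (1.53), Ccr1 (1.30), Dst (1.32), Socs2 (1.17), the actin capping gene Capg (0.93) and Ctla4 (0.50 log2) rose. Cytotoxic genes fell in 7 of 11 (camera adjusted p = 1.74e-12; adjusted p = 0.102 with an estimated correlation) and Th1 genes in 4 of 13 (adjusted p = 3.48e-07; adjusted p = 0.102 with an estimated correlation). In cluster 6, with its Th1 transcripts, 161 genes were higher and 257 lower among 8035 tested (19.9% separated). Il17a rose (log2 fold change 1.17, SE 0.06, adjusted p = 5.26e-14), as did the Th17 homing receptor Ccr6 (0.97), Nt5e (1.38), Vdr (3.94), Syp (3.26) and Il2ra (0.57 log2), and Tmeff2 went from 0 to 69 UMIs, at least 34.2-fold higher. Gzmk (log2 fold change -3.08, SE 0.31, adjusted p = 2.14e-06), Cxcr3 (-2.39), Ifng (log2 fold change -1.78, SE 0.09, adjusted p = 4.07e-12), Tbx21 (-1.53), Ctsw (-1.68), Fasl (-1.44) and Satb1 (-1.33 log2) fell. Th1 genes fell in 4 of 14, or 9 adjusted over the list alone (adjusted p = 3.81e-07; adjusted p = 0.357 with an estimated correlation), cytotoxic genes in 4 of 7 (adjusted p = 2.43e-06; adjusted p = 0.357 with an estimated correlation), and Th17 genes rose in 5 of 15 (adjusted p = 0.0051; adjusted p = 0.357 with an estimated correlation).

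In Tfh-like cells 20 genes were higher and 6 lower in tdTomato+GFP+ cells among 5068 tested (15.0% separated), or 55 in all with replicate number as a block. Socs2 (2.63), Il17a (2.28) and Cpe (2.57 log2) rose, and Ccl5 had 184 UMIs against 0 (at least 7.4-fold lower). Cycling cells gave 132 higher and 153 lower of 7354 (20.1% separated), with Vdr (2.41) up and Itgae (-3.22), Ifng (-2.85), Cxcr5 (-2.62) and Satb1 (-2.07 log2) down. Cluster 4 gave 49 higher and 70 lower of 7604 (18.0% separated), or 226 in all with replicate number as a block, with Vdr (4.28) and the eosinophil cytokine Il5 (2.46) up and Gzmk (-2.29) and Ikzf2 (-1.82 log2) down. Cluster 8 gave 18 higher and 30 lower of 6574 (14.3% separated), or 94 in all with replicate number as a block, with Il17a (2.72) and Vdr (2.60) up and Itgae (-3.26), Penk (-3.07) and Ikzf2 (-2.14 log2) down. Cluster 11 gave 72 higher and 77 lower of 3721 (20.6% separated), with Cpe (2.86) and Il17a (2.63) up and Ccl5 (-4.44) and Ikzf2 (-2.39 log2) down. There Pglyrp1 had 43 UMIs against 0 (at least 9.0-fold lower) and Cd7 was lower by a ratio of 38.4 (95% counting interval 6.6 to 1542.2). Clusters 8 and 11 are those that stromal, heat shock or epithelial transcripts lead. Il17a in cells without a cluster stood at 3817 CPM (SD 2412) in the tdTomato+GFP+ and 787 CPM (SD 217) in the tdTomato-GFP- gate. Its tdTomato+GFP+ level in cluster 5, cluster 6, Tfh-like cells and cluster 8 lay below the first of these values. Ccl20, Il17f and Cpe are also among the leading genes of Th17-like clusters. Their levels in cells without a cluster are not given here, so free RNA is not excluded for their rises in other classes.

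The T cell receptor sequences were compared for clonal make-up. A clonotype is a pair of alpha and beta CDR3 nucleotide sequences. At 1267 drawn cells per replicate, 81.3% (SD 9.27) of tdTomato+GFP+ and 47.1% (SD 1.18) of tdTomato-GFP- cells belonged to clonotypes of 2 or more cells, a difference of 34.2 points (exact permutation test, two-sided, p = 0.1). The largest clonotype held 7.54% against 2.38% and the 10 largest held 31.2% (SD 16.98) against 11.6% (SD 1.45) of cells. Replicate 1 of the tdTomato+GFP+ gate stood apart, with 91.9% of drawn cells expanded, 50.8% in the 10 largest clonotypes and 143 cells, 10.4%, in the largest. Cells of the 10 largest clonotypes were Th17-like in 78.7% of cases in the tdTomato+GFP+ and 31.4% in the tdTomato-GFP- gate. Replicates of the same number in the 2 gates shared 19, 23 and 33 clonotypes, 75 together, which held 8.94% (SD 1.85) of tdTomato+GFP+ cells and 4.66% (SD 2.18) of tdTomato-GFP- cells. Replicates of different numbers shared 8 clonotypes over 6 pairs, holding 0.149% of tdTomato+GFP+ cells. In tdTomato-GFP- cells of the shared clonotypes, 2.35% (SD 0.666, 8 of 310 cells) had a Foxp3 UMI, against 20.9% (SD 2.37) of tdTomato-GFP- cells of other clonotypes and 18.3% (SD 3.01) of those of other expanded clonotypes. Of their tdTomato+GFP+ cells 30.3% (SD 2.56) had a Foxp3 UMI. Th17-like cells made up 36.7% (SD 3.63) of the tdTomato-GFP- cells of shared clonotypes, 10.8% of those of other clonotypes and 17.6% (SD 4.49) of those of other expanded clonotypes.

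**Figure D4:**
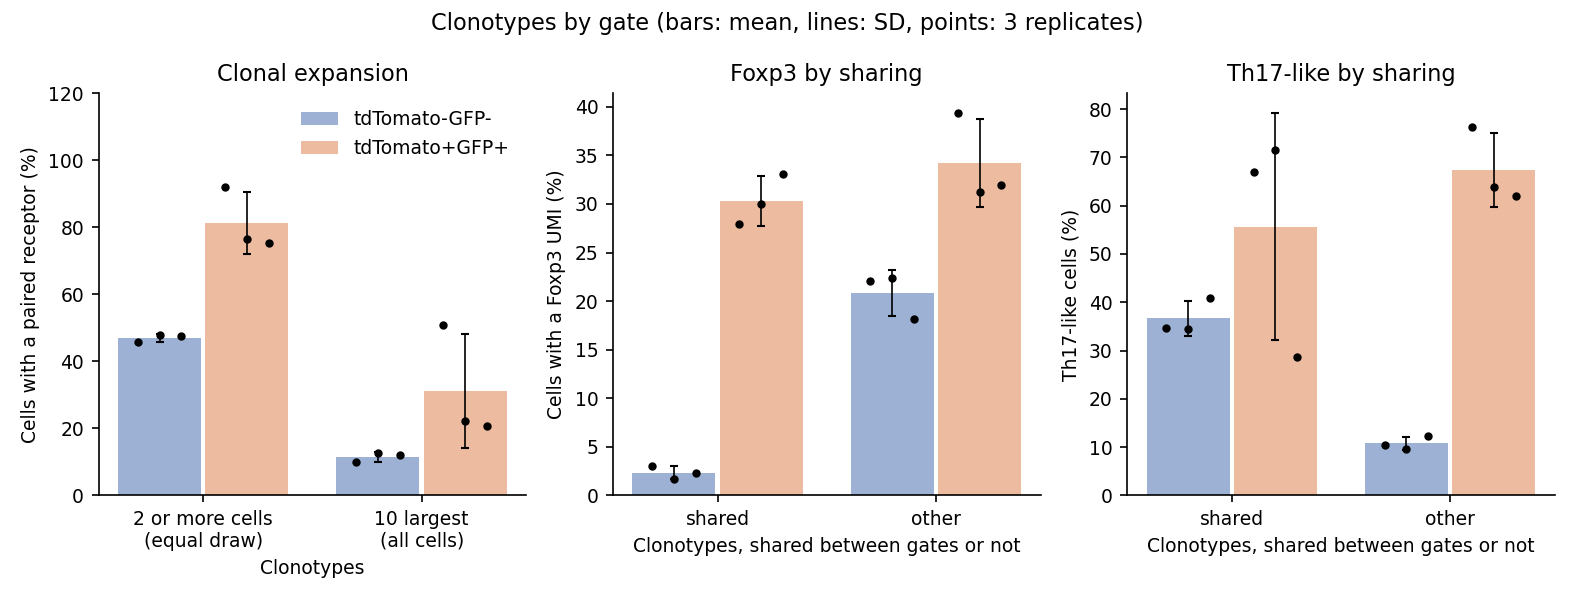
Share of cells with a paired receptor in clonotypes of 2 or more cells (1267 cells drawn per replicate) and in the 10 largest clonotypes, and the shares of cells with a Foxp3 UMI and of Th17-like cells in clonotypes shared between gates or not, with bars for the mean, lines for the SD and points for the 3 replicates. Expanded clonotypes hold 81.3% of tdTomato+GFP+ and 47.1% of tdTomato-GFP- cells, and tdTomato-GFP- cells of shared clonotypes have a Foxp3 UMI in 2.35% of cases.

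Of 52 V genes tested with each clonotype counted once, TRBV31 alone passed, at 8.04% (SD 0.374) of tdTomato-GFP- and 5.44% (SD 1.18) of tdTomato+GFP+ clonotypes (edgeR, log2 fold change -0.75, SE 0.18, adjusted p = 0.00514), and it did not pass with replicate number as a block. In all, 8 V genes had an unadjusted p below 0.05, among them the TRBV12-2 and TRBV13-2 group (-0.44, adjusted p = 0.105) and TRBV29 (0.88, adjusted p = 0.147). Clonotypes of 2 or more cells spread over 2 or more classes in 67.3% (SD 5.21) of 705 cases in the tdTomato+GFP+ and 77.3% (SD 1.87) of 919 in the tdTomato-GFP- gate, against 75.0% and 93.5% under shuffled class labels, and below the shuffled mean in all replicates but tdTomato+GFP+ replicate 1 (71.6% against 70.7%). In the tdTomato-GFP- gate 35 clonotypes joined Th17-like cells and cluster 5, against 176.9 under shuffling, 64 joined Th17-like and Th2-like cells (219.8 shuffled) and 30 joined Tfh-like cells and cluster 5 (96.0 shuffled), whereas 90 joined Th2-like cells and cluster 8 (91.5 shuffled). In the tdTomato+GFP+ gate 114 joined Th17-like and Th2-like cells (220.6 shuffled), 39 joined Th17-like cells and cluster 5 (69.7 shuffled) and 55 joined cluster 6 and cycling cells (48.8 shuffled).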

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

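The tests of free RNA, of a lane effect alike in all cells and of sorting carry-over by Foxp3 share were chosen after the results had been seen, as were the splits of the gene counts over all cells and within classes. Those of make-up, of the X chromosome in use and of carry-over by Th17-like share, and the splits of lists, V genes and gate effects between classes, were fixed before. The test of expanded clones was written before its value was seen, on a setting added after the data had been seen. The gate effect differed between classes, a difference between groups that no label describes. Between Th17-like cells and cluster 5 it differed at 328 of 9316 genes, between Th17-like and Th2-like cells at 128 of 9971, between Th17-like cells and cluster 6 at 22 of 9009, and between Th2-like cells and cluster 6 at 2 of 9090, Itgav (1.05 log2 units more in cluster 6) and Cd6 (-0.70), both adjusted p = 0.0482 and, like the others that follow, named after their values were seen. Against Th17-like cells, cluster 5 had a higher gate effect for Tnfsf8 (by 2.54 log2 units, adjusted p = 1.47e-08), Cxcr6 (by 2.02) and Cd40lg (by 3.46) and a lower one for Cd81 (by -3.94), Flicr (by -4.36) and Il2ra (by -1.80). Th2-like cells had a higher effect than Th17-like cells for Cd5 (by 1.08, adjusted p = 1.17e-05) and Satb1 (by 1.21) and a lower one for Il2ra (by -0.81, adjusted p = 0.0240). Cluster 6 had a higher effect than Th17-like cells for Il17a (by 0.83, adjusted p = 5.81e-06). Il17a in tdTomato+GFP+ cells of cluster 6 (2149 CPM) lay below that in cells of the lane without a cluster (3817 CPM, SD 2412), so free RNA is not excluded there. Cells without a hashed replicate, data that the comparisons leave out, had medians of 7675.5 UMIs in the tdTomato+GFP+ lane (2504 cells) and 7103 UMIs in the tdTomato-GFP- lane (2217 cells), against 3632 and 3860 among assigned cells.

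For Foxp3 the gate effect in cluster 5 less that in Th17-like cells was -3.99 (adjusted p = 0.000128), while Th2-like less Th17-like cells (-1.56, adjusted p = 0.0543) and cluster 6 less Th17-like cells (-1.13, adjusted p = 0.590) did not pass. A lane effect that acts alike on all cells would leave the folds equal. Taken from the separate fits they differed by 3.95 log2 units (SE 0.344) with opposite signs. The pattern was defined by those signs, so this speaks only against such an effect as the sole cause. A lane effect added to another difference is not excluded. Free Foxp3 RNA as the source of the Th17-like signal would give a like level in cells without a cluster. Th17-like cells of the lane stood 3.51 to 6.69 times higher in the 3 replicates, which speaks against it as the whole source. The cells without a cluster numbered 22, 50 and 17 and held 5, 15 and 2 Foxp3 UMIs, so these ratios carry a wide counting error. Some carried both receptor chains, so they are not a pure background. A biological hypothesis, not tested here, is that cells of the inserted allele transcribe the Foxp3 locus at a middling level. Their mean was 144 CPM (SD 12.2) in Th17-like cells and 191 CPM (SD 33.1) in cluster 5, which were not tested against each other. In the tdTomato-GFP- gate cluster 5 reached 839.6 CPM and Th17-like cells 35.4 CPM. The transcript with the insert and the intact one may also be counted unequally, which was not tested. The sort by GFP selects cells that transcribe the inserted allele, and no test here separates that from a change in regulation.

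Il17a, Il17f and Ccl20 were higher in tdTomato+GFP+ cells by a mean log2 fold of 3.05. A few expanded clones could carry this, but with 1 cell per clonotype the mean was 3.58, or 117% of the value, which excludes them (Il17a 3.03, adjusted p = 7.41e-06, up to 0.867 over all 17 alternatives). Free RNA, which reaches all droplets of a lane alike, is excluded as the whole source over all cells. Of tdTomato+GFP+ cells of at least median depth, 15.7% to 34.1% held under 0.1 times the mean UMIs of the 3 genes. Free RNA is not excluded for any of the 3 genes in classes other than Th17-like. Make-up of the gates by cluster could also account for it. At equal cells per cluster the mean fell to 0.986, or 32.3% of the value, between the bounds set beforehand, so the test cannot tell for the 3 genes together. By gene, Il17a was 0.33 (adjusted p = 0.867, its highest) and Il17f 0.47 (adjusted p = 0.783, its highest), so most of their folds over all cells was lost. Ccl20 was 2.16 (adjusted p = 0.0128, at most 0.0305 elsewhere) and alone kept its call there. All 3 genes lead the Th17-like clusters, so equal cells per cluster also match the gates in part on these genes.

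Clonotypes found in both gates of 1 animal form the third pattern. That their tdTomato-GFP- cells use the same X chromosome, and so hold few cells that transcribe Foxp3 once GFP+ cells are sorted away, predicts few Foxp3 UMIs, and 2.35% of them had one against 20.9% of other cells (SD 2.37), lower in 3 of 3 animals by the margin set beforehand, which is consistent with this hypothesis. Carry-over of tdTomato+GFP+ cells by the sort would give a like Foxp3 share, but the share was at most 0.109 times that of the tdTomato+GFP+ cells of the same clonotypes, which speaks against it. The test of carry-over by the Th17-like share, the one fixed beforehand, stayed undecided, with ratios of 0.482 to 1.43. Other reasons for a low Foxp3 share in clones of non-Treg origin remain open.

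With 10 splits of 6 replicates into 3 and 3, the splits are too few for a share under 0.05. The real split alone gave its count in each case but that of gene lists. Each other split mixes the gates within a group, so the gate difference adds to the spread there and tends to lower the gene calls. A low count in other splits thus does not show how many genes would be called without a difference. The counts of the real and the highest other split were 3153 and 0 over all cells, 2414 and 0 against Foxp3 UMI-positive cells, 1129 and 0 in Th17-like cells, 231 and 0 in Th2-like cells, 241 and 2 in cluster 5, 418 and 1 in cluster 6, 149 and 0 in cluster 11, 119 and 1 in cluster 4, 48 and 0 in cluster 8, 285 and 3 in cycling cells and 26 and 8 in Tfh-like cells. For the last pair the highest among the 3 other splits that part all replicate numbers was 0 and 1. For gene lists the real split called 12, as did 1 other that parts a single pair, so 2 of 10 reached it. Among the other splits that part all pairs the highest count was 7. All 9 other splits called lists, with 2 as the lowest count. Camera at its fixed correlation thus called lists for groupings that mix the gates. A small camera adjusted p over all cells therefore does not by itself show a gate difference. No such counts are given here for lists within classes or against Foxp3 UMI-positive cells. For gate effects between classes (328, 128, 22 and 2) and V genes (1) no other split gave a call.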

How the results depend on the processing

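Of the named genes, 4264 results under an alternative kept direction and side of the threshold, 494 became weaker and 80 stronger, while 222 of the summary values stayed, 91 moved and 7 became stronger. Upper-quartile normalization left 386 of 388 named genes as they were, DESeq2 342 of 366, and leaving out single replicates kept 1981, weakened 280 and strengthened 22. For every value that changed in what follows, the cause was not tested, except that the 1.5-fold minimum, fewer cells and fewer replicates lower counts by construction. A count is taken as moved where it changed by more than 1.5-fold. The replicate block gave 2060 genes higher and 2073 lower over all cells and moved no other summary than those given here. Simulated 2-fold changes were called least often in Tfh-like cells (41.8%) and cluster 5 (50.7%). The settings with 1 cell per clonotype, the replicate block for V genes and cluster 5 of the tdTomato-GFP- gate were chosen after seeing the data.

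Over all cells, genes higher and lower in tdTomato+GFP+ cells numbered 188 and 286 with the 1.5-fold minimum, 93 and 189 at equal cells per cluster and 718 and 814 with 1 cell per clonotype. Leaving out single replicates gave 911 (without tdTomato+GFP+ replicate 2) to 1456 higher. Against Foxp3 UMI-positive cells the counts were 175 and 303 with the 1.5-fold minimum, 98 and 142 for cluster 5 of both gates and 609 and 760 with 1 cell per clonotype. With a Foxp3 UMI required in both gates Tff1 (-3.35), Hspb1 (-4.19), Il10 (-0.95) and Tcf7 (0.22 log2) did not pass, and with at least 2 Foxp3 UMIs the counts were 1031 and 1319. Without tdTomato+GFP+ replicate 2 they were 562 and 856, and with other replicates left out they reached 1095 and 1277. Of the called gene lists, 0 rose and 0 fell with an estimated correlation, and 2 (without tdTomato-GFP- replicate 3) to 4 rose when single replicates were left out.

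For Th17-like cells (1129 genes) the counts were 1726 with the replicate block, 153 with the 1.5-fold minimum, 273 with 1 cell per clonotype and 612 (without tdTomato-GFP- replicate 1) to 1053 without single replicates. For Th2-like cells (231) they were 571 with no filter, 363 with the block, 25 with the 1.5-fold minimum, 118 with 1 cell per clonotype and 93 (without tdTomato+GFP+ replicate 2) to 415 (without tdTomato+GFP+ replicate 1). For cluster 5 (241) they were 495 with no filter, 60 with the 1.5-fold minimum, 49 with 1 cell per clonotype and 97 to 421 (without tdTomato+GFP+ replicates 2 and 1). For cluster 6 (418) they were 69 with the 1.5-fold minimum, 213 with DESeq2, 117 with 1 cell per clonotype and 251 (without tdTomato+GFP+ replicate 2) to 434. For Tfh-like cells (26) they were 83 with no filter, 55 with the block, 6 with the 1.5-fold minimum, 3 with 1 cell per clonotype and 3 (without tdTomato-GFP- replicate 1) to 28. For cycling cells (285) they were 504 with no filter, 45 with the 1.5-fold minimum, 132 with DESeq2, 19 with 1 cell per clonotype and 131 (without tdTomato-GFP- replicate 1) to 352. For cluster 4 (119) they were 322 with no filter, 226 with the block, 19 with the 1.5-fold minimum, 26 with 1 cell per clonotype and 39 (without tdTomato+GFP+ replicate 2) to 168. For cluster 8 (48) they were 154 with no filter, 94 with the block, 10 with the 1.5-fold minimum, 15 with 1 cell per clonotype and 15 (without tdTomato-GFP- replicate 2) to 137 (without tdTomato+GFP+ replicate 1). For cluster 11 (149) they were 235 with no filter, 23 with the 1.5-fold minimum, 70 with DESeq2 and 42 (without tdTomato+GFP+ replicate 2) to 209.

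Tested in edgeR on numbers of cells, the shares of Th17-like cells (2.55 log2), Th2-like cells (-1.11), Tfh-like cells (-2.71), cluster 4 (-1.29), cluster 5 (-2.96), cytotoxic-like (-2.48) and naive or central memory-like cells (-3.59) passed. The falls among them are shares of all cells too, lowered together by the larger Th17-like share. The exact test cannot reach the threshold. Of V genes (1 called), 0 were called with each cell counted once (9 at an unadjusted p below 0.05), 0 with the block (8 unadjusted) and 0 to 2 without single replicates. The clonal expansion difference of 34.2 points was 31.1 over all cells, 33.5 by beta chain and 28.8 to 37.1 without single replicates. Sharing at different numbers rose from 0.149% to 0.499% by beta chain and 0.383% by amino acids. Of clonotypes of 5 or more cells, 97.4% (tdTomato-GFP-) and 87.0% (tdTomato+GFP+) spread over classes.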

Other observations

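Several genes moved in the same direction in several classes, though not in all. Vdr was higher in tdTomato+GFP+ cells in cluster 4 (log2 fold change 4.28, SE 0.47, adjusted p = 2.12e-05), cluster 6 (log2 fold change 3.94, SE 0.39, adjusted p = 2.08e-07), cluster 5 (3.97), Th17-like cells (2.91) and cycling cells (2.41 log2), and it encodes the receptor for the active form of vitamin D. Socs2, a target of STAT5 signalling, rose in Tfh-like (2.63), Th17-like (1.23) and Th2-like cells (1.17) and in cluster 5 (1.01 log2). Ikzf2 fell in cluster 11 (log2 fold change -2.39, SE 0.35, adjusted p = 0.000164), cluster 8 (-2.14), cluster 4 (-1.82), Th17-like (-1.04) and Th2-like cells (-0.83 log2). It differed little in Tfh-like cells (-0.05 log2, edgeR adjusted p = 0.977), and its fall in cluster 5 did not pass. Since all classes share the lane, no overlap between them was tested.

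Further gene lists were called within classes. In Th17-like cells the cell cycle list had 7 of 27 genes down (camera adjusted p = 0.0169; adjusted p = 0.643 with an estimated correlation) and glycolysis 2 of 17, with Hk2, which encodes a hexokinase, at -2.17 (adjusted p = 0.0254; adjusted p = 0.489 with an estimated correlation). In cycling cells Tfh genes fell in 6 of 13 (adjusted p = 1.9e-05; adjusted p = 0.359 with an estimated correlation) and cell cycle genes rose in 5 of 30 (adjusted p = 0.00566; adjusted p = 0.745 with an estimated correlation). In cluster 5 Th2 genes rose in 2 of 10, or 5 adjusted over the list alone (adjusted p = 0.0123; adjusted p = 0.513 with an estimated correlation). In cluster 4 Th1 genes fell in 3 of 14 (adjusted p = 2.37e-05; adjusted p = 0.277 with an estimated correlation).

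Of the tests on the hashtags, that on the main hashtag share was fixed beforehand and that on sharing between lanes was chosen after the result had been seen. Within a lane, clonotypes also occurred in 2 or more hashed replicates, with 21, 3 and 9 in the tdTomato-GFP- and 13, 1 and 12 in the tdTomato+GFP+ gate for the replicate pairs 1 and 2, 1 and 3, and 2 and 3. Cells outside the main replicate of such clonotypes numbered 36 (0.5% of cells with both chains, 33 clonotypes) and 31 (0.507%, 24 clonotypes). Their median main hashtag share differed from that of other cells by 1.42 points in one lane and -0.437 points in the other, 0.493 points on average, so that the test went opposite ways in the lanes. Sharing between different replicate numbers of the 2 lanes was 0.136 times that within a lane. In the tdTomato+GFP+ gate no clonotype joined Th17-like and cytotoxic-like cells (14.2 under shuffling), and in the tdTomato-GFP- gate 2 did (31.4 under shuffling), where the permutation p was 0.0020, the smallest that 1000 shuffles with a two-sided reading give.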
